A study of Mus musculus with 2 samples.

How the data were processed

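H3K27ac ChIP-seq peak lists of mouse limb at embryonic day 11.5 were analysed. The labels name 2 biological replicates with separate biosamples, pooled from 109 and 88 embryos. Both were placed in 1 group from their tissue and antibody labels, and the replicate numbers are those of the labels.

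The authors deposited 4 lists in narrowPeak format on mm10. Per the file headers, the list of each replicate was derived from that replicate's alignments and further files, the pooled list from the alignments of both replicates, and the replicated list from the other 3. The aligner, the peak caller, the peak threshold and the rule for the replicated list were not given in the sources used here. A possible control experiment named in the labels was not analysed here. Each deposited line holds a display score, which was not used, and a fold enrichment over background (a ratio above 1). It also holds the −log10 of a p-value and of a q-value, as the authors' caller gave them. The deposited position of the summit within the peak was used to place each peak. These values belong to single peaks and were used to describe, rank and filter peaks within a list.

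In the lists of both replicates, the fold matched (h + 1)/(b + 1) and the p-value the Poisson probability of more than h fragments at background b, for a whole number h, within 0.001 in −log10 p for 100% of peaks. The summit height h and the background b recovered this way describe the counts behind each call, since total fragments were not used here. Whether b came from the replicate itself or from a control was not stated, so it is no measure of depth. Intervals on heights are exact Poisson intervals at 95% and cover counting error only.

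Peaks were placed on GENCODE M21 genes and the RefSeq sequence of GRCm38 patch 6, which is the mm10 build; every chromosome held its highest peak end. Peaks on unplaced scaffolds were left out of all steps that use genes. A promoter peak overlapped the 1 kb on either side of a TSS of a protein-coding transcript, and a distal peak lay with its whole length more than 2.5 kb from every annotated TSS. Where a gene had several promoter peaks, the fold is that of the highest. Folds given without a replicate are those of the replicated list, which can lie above the folds of both replicates. Distal peaks were given to the nearest protein-coding TSS within 1 Mb.

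Overlap between lists needed 1 bp and was compared with 1000 circular shifts along each chromosome, one-sided. Promoter peaks of 31 gene lists were compared with the other genes among 21853 protein-coding genes by Fisher's exact test, two-sided. Distal peaks of the lists were compared with 10000 random lists of the same size matched in 20 bins of territory length, the stretch in which a gene has the nearest TSS. The smallest two-sided p these can give is 0.00019998. Motif shares of 24 consensus strings were compared between 500 bp summit windows and control windows 10 to 100 kb away, matched within 2 percentage points of GC, by Fisher's exact test. A control was found for 12932 of 13975 distal peaks. Each family of tests was adjusted by Benjamini-Hochberg, and a call needed an adjusted p under 0.05. Genes and windows are not replicates, so these p-values describe this map. Values from the list of each replicate are given for some of the results. Distal peaks were stitched at 12.5 kb.

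The gene lists, motifs, tests and settings were fixed before the data were examined, as was the rule for named genes. Per list, the rule took the 4 members with the highest promoter fold and up to 4 members without a promoter peak in alphabetical order. Over all genes it took the 10 with the highest promoter fold, the 10 with the widest promoter peak and the 10 with the most distal peaks, and it added the 10 longest clusters. It also fixed Shh, Lmbr1, the Hoxa and Hoxd clusters, Pitx1, Tbx4, Tbx5, Grem1, Fgf8, Fgf10, Gli3, Sox9 and Prrx1. Genes outside it are marked as named after their values were seen. The marker lists also cover cell types that limb tissue could hold besides mesenchyme. Of the 12 erythroid symbols 11 were in the annotation.

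Alternatives were stricter −log10 q values (2 and 5), overlaps of 50%, promoter windows of 500 bp and 2.5 kb, the pooled list, each replicate's own list, random lists matched on promoter CpG ratio or promoter peaks, a 100 kb limit, stitching at 5 and 25 kb, 1 kb motif windows and controls not matched on GC. Added after seeing the data were motifs without repeats, summit heights of at least 10 fragments, replicated peaks overlapped by a peak of each replicate and a −log10 q of 20.

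The steps were tested on simulated data. For the overlap of replicates, a planted share of 40% came back as 40.0% over 20000 peaks. This checks the counting only, since all other peaks were placed off the target. For promoter lists over 21853 genes, 68.0% of lists of 14 genes with 80% marked were called and 1.00% of unchanged lists. For distal lists, 66.7% of lists of 14 genes with long territories, raised 4-fold, had a p under 0.05 and 1.67% of unchanged lists. The motif step called the planted motif and 0 others over 3000 windows of random sequence, so GC matching and the placing of control windows were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.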

Results

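H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the limbs of mouse embryos at 11.5 days of gestation, when the limb bud is a core of mesenchyme under an ectodermal cover. The labels did not say whether forelimbs, hindlimbs or both were taken. The design held 1 group of 2 biological replicates, pooled from 109 and 88 embryos of the B6NCrl strain and of both sexes, and no control group, so no treatment effect could be tested. The data were 4 peak lists on the mm10 build: 52536 peaks of replicate 1, 79667 peaks of replicate 2, 48064 peaks of both replicates together (the pooled list) and 28283 peaks that the authors listed as replicated. The comparisons open to this design were between the replicates, between peaks and shifted positions, and between gene groups within the map.

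The replicates held 66101.5 ± 19184.5 peaks (SD, n = 2). The median peak width was 261 bp in replicate 1 and 268 bp in replicate 2, and the peaks covered 21.4 Mb and 34 Mb. Replicated peaks were wider, with a median of 508 bp, and covered 20.7 Mb or 0.760% of the genome. The total number of sequenced fragments was not given in the lists. The summit heights recovered from each peak's fold and p-value gave the fragments behind the calls: the median was 9 fragments in replicate 1 and 7 in replicate 2, and 53.04% and 72.3% of peaks had fewer than 10. The lowest background level, taken near the bottom of the recovered range, was 1.64 fragments in replicate 1 and 1.2 in replicate 2. Its source was not stated, and 44.5% and 41.0% of peaks lay at it.

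The first comparison asked how far the replicates marked the same places. A peak of replicate 2 overlapped 29885 peaks of replicate 1 (56.9%), against a mean of 2.54% and a highest value of 3.32% over 1000 circular shifts. A peak of replicate 1 overlapped 26903 peaks of replicate 2 (33.8%), against a mean of 1.67% and a highest value of 2.05%. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. Promoter peaks overlapped more often than distal ones, at 84.1% against 46.4% in replicate 1 and 63.7% against 25.5% in replicate 2. The share rose with the strength of the peak: in replicate 1 it went from 28.3% for a −log10 q under 1 to 96.7% between 5 and 10, and in replicate 2 from 9.93% to 79.4%. All 2167 peaks of replicate 1 and all 3459 peaks of replicate 2 with a −log10 q of 20 or more were overlapped. With 50% of both peaks required, the shares were 29.9% and 19.7%, and with both lists at a −log10 q of 5 or more they were 87.6% and 59.3%. They were 51.9% and 45.2% with equal numbers of peaks, and 68.3% and 65.9% for summits of at least 10 fragments, a limit chosen after seeing the data.

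**Figure D1:**
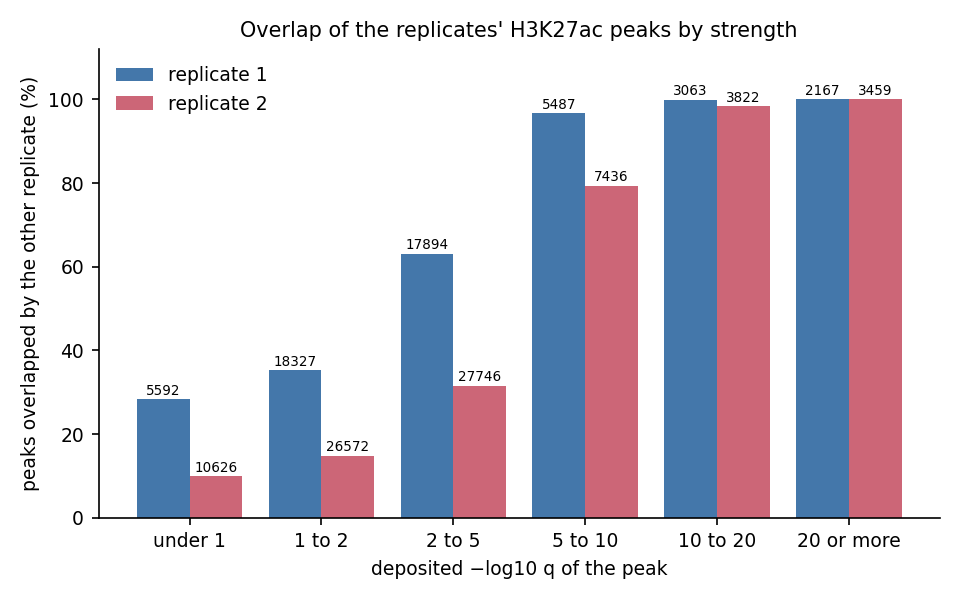
Share of each replicate's peaks overlapped by at least 1 bp of a peak of the other replicate (y axis, percent) in bins of the deposited −log10 q (x axis), with blue bars for replicate 1, red bars for replicate 2 and the number of peaks in the bin printed above each bar. The bars reach 100% for the 2167 and 3459 peaks with a −log10 q of 20 or more, while peaks with a −log10 q under 1 reach 28.3% in replicate 1 and 9.93% in replicate 2.

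Across the 29885 overlapping pairs, the fold enrichments of the replicates had a Spearman correlation of 0.598. This correlation is across peaks, which are not independent replicates, so no p-value is given. It was 0.681 over promoter peaks and 0.479 over distal peaks. The replicated list was derived from the other lists, so its overlap with each replicate is in part a product of the authors' rule. Of its 28279 peaks on assembled chromosomes, 24693 (87.3%) were overlapped by a peak of each replicate, 2771 by replicate 2 alone, 778 by replicate 1 alone and 37 by neither. Each of the 28279 had the coordinates of a pooled peak. The authors' rule for this list was not stated in the labels or headers.

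Replicated peaks lay at promoters far more often than the same peaks did after shifting. Of the replicated peaks, 10484 (37.1%) reached within 1 kb of a protein-coding transcription start site (TSS), 10.8 times the 3.43% found after circular shifts, of which the highest was 4.27% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The share was 28.4% in the pooled list, 25.6% in that of replicate 1 and 20.1% in that of replicate 2. A further 3820 peaks (13.5%) were neither promoter nor distal, and 13975 (49.4%) lay more than 2.5 kb from every annotated TSS. Promoter peaks had a median fold of 6.33 and a median width of 623 bp, and distal peaks 4.33 and 449 bp. Among distal summits, 7063 (50.5%) were in introns, 6461 (46.2%) between genes and 451 (3.23%) in exons. Their median distance to the nearest protein-coding TSS was 40.1 kb, and 3388 (24.2%) were more than 100 kb away. The X chromosome carried 2.83 replicated peaks per Mb and chromosome 11 carried 19.2.

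Tnrc18 had the highest promoter fold, 64.4, in a peak of 11204 bp on chromosome 5 (142813214 to 142824417). Setd1b, a histone H3 lysine methyltransferase, followed at 61.4, with 25.04 in replicate 1 and 63.2 in replicate 2, Gas1, a membrane protein that takes part in Hedgehog reception, at 54.6, and Arid2, a chromatin remodelling subunit, at 53.5. Gjc1 (53), Arrdc3 (51.4), Bicral (51.2) and Zc3h6 (50.6) were also among the 10 highest. Replicates 1 and 2 both lay below the replicated fold at Tnrc18 (47.0 and 62.0), Gjc1 (38.3 and 49.5), Arrdc3 (37.6 and 46.4) and Bicral (37.2 and 36.3). At Gas1 (36.4 and 57.3) and Arid2 (36.04 and 54.1) replicate 2 lay above it. Brd2 and H2-DMa shared 1 peak with a fold of 51.9, with 31.1 in replicate 1 and 54.6 in replicate 2. The widest promoter peak, 16020 bp on chromosome 6 (52231387 to 52247406), ran over Hoxa10 and Hoxa11, and one of 12434 bp (52215803 to 52228236) over Hoxa7 and Hoxa9. Other genes with the widest promoter peaks were Mecom (12382 bp), Zmynd8 (10321 bp), Cpa2 (9672 bp), the tendon regulator Scx (9352 bp) and the mesenchymal growth factor receptor Pdgfra (9339 bp). These widths are those of pooled peaks. The widest peak of any kind was 9329 bp in replicate 1 and 15927 bp in replicate 2, so no peak of replicate 1 reached the widths named here. In all, 8746 of 21853 protein-coding genes (40.02%) had a replicated promoter peak, compared with 43.2% in the list of replicate 1 and 49.7% in that of replicate 2.

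Regulators of limb mesenchyme carried promoter acetylation throughout. All 27 genes of the limb transcription factor list had a replicated promoter peak, against 39.9% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 2.77e-10), and all 27 had one in each replicate. Prrx1, a homeobox gene of early limb mesenchyme, had a fold of 44.7 in a peak of 8296 bp on chromosome 1 (163307486 to 163315781). Its summit height was 92 fragments in replicate 1 (exact Poisson 95% interval 74.2 to 113) and 88 in replicate 2 (70.6 to 108). Shox2, needed for growth of the proximal limb, had a fold of 36.2, Tbx15, a T-box gene of limb and skin mesenchyme, 33.6, and Gli3, the Hedgehog-responsive repressor of anterior limb, 32.8. The list also stood above random lists matched on promoter CpG ratio (adjusted permutation p = 0.00207).

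The posterior genes of the Hoxa and Hoxd clusters pattern the limb from shoulder to digit. All 10 genes of the Hoxa9 to Hoxa13 and Hoxd8 to Hoxd13 list had a replicated promoter peak, in 9 distinct peaks (Fisher's exact test, adjusted p = 0.000787). Folds were 27.4 at Hoxa10 and Hoxa11, 27 at Hoxa9, 25.1 at Hoxd8, 18.7 at Hoxa13 and 9.23 at Hoxd13. In replicate 1 they were lower at Hoxa9 (13.8), Hoxd8 (15.8) and Hoxa13 (11.5). Hoxb genes had a replicated promoter peak at 4 of 10 members, led by Hoxb4 at 11.3 (Fisher's exact test, adjusted p = 1), and Hoxc genes at 6 of 9, led by Hoxc10 at 10.3 (Fisher's exact test, adjusted p = 0.251). In the list of replicate 2 these counts were 9 of 10 for Hoxb and 9 of 9 for Hoxc, which both passed as higher (Fisher's exact test, adjusted p = 0.0268 and 0.00635), and in that of replicate 1 they were 5 and 6. The folds in replicates 1 and 2 were 7.21 and 13.2 at Hoxb4 and 6.81 and 10.9 at Hoxc10. Against CpG-matched random lists the posterior Hox list did not pass the threshold (adjusted permutation p = 0.102).

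The genes that separate forelimb from hindlimb were all marked. Tbx5, required for the forelimb, had a fold of 22.9 in a 9261 bp peak on chromosome 5 (119828775 to 119838035). The hindlimb genes Pitx1, Tbx4 and Isl1 had folds of 19.2, 14.8 and 4.22. Tbx5 stood above Pitx1 in replicate 2 (26.2 against 17.3) but not in replicate 1 (10.9 against 15.6). The list did not pass the threshold (4 of 4, Fisher's exact test, adjusted p = 0.0530), but did with a 500 bp window (0.0449) and with replicated peaks overlapped by each replicate (0.0448), the latter chosen after seeing the data.

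Targets of the signals that drive limb outgrowth were frequently acetylated. All 9 genes of the FGF response list had a promoter peak (Fisher's exact test, adjusted p = 0.00136), led by the feedback inhibitors Dusp6 at 30.8, Spred1 at 29.5 and Spry2 at 27.9, and the receptor gene Fgfr2 at 25.3. In the Hedgehog and BMP list, 11 of 14 genes had one (Fisher's exact test, adjusted p = 0.0146). Ptch1, the Hedgehog receptor and target, had a fold of 36.2. Id2, a BMP target, had 24.5 (16.1 and 22.4 in replicates 1 and 2) and Gli2 21.8. The members without one were the ligand gene Shh, the BMP antagonist gene Grem1 and Hhip, of which Grem1 had a peak with a fold of 2.62 in replicate 2. Of the retinoic acid genes, 6 of 8 had a peak, Rarg at 29.0 and Crabp2 at 21.4 among them (Fisher's exact test, adjusted p = 0.115, and 0.0272 with a 2.5 kb window, where 87.5% had one). Against CpG-matched random lists neither the FGF list (adjusted permutation p = 0.197) nor the Hedgehog and BMP list (0.246) passed the threshold, and at a −log10 q of 5 or more the Hedgehog and BMP call ended (64.3%, Fisher's exact test, adjusted p = 0.0507).

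Genes of early cartilage and of connective tissue matrix were frequently marked. Chondrogenic genes had promoter peaks at 13 of 17 members (Fisher's exact test, adjusted p = 0.0146), with folds of 21.9 at Sox9, the regulator of cartilage fate, 16.0 at the cartilage collagen gene Col2a1, 15.1 at Col9a1 and 10.6 at Sox6. Acan and Comp, which encode proteins of mature cartilage matrix, had no promoter peak in any of the 4 lists. Fibroblast and matrix genes had peaks at 13 of 14 members (Fisher's exact test, adjusted p = 0.000611), with folds of 28.2 at Pdgfra, 19.3 at Fn1 and 18.5 at Vcan, and Postn as the exception. Both lists passed against CpG-matched random lists (adjusted permutation p = 0.00723 and 0.00207). The chondrogenic call ended when only replicated peaks with a −log10 q of 5 or more were kept (Fisher's exact test, adjusted p = 0.182). Osteoblast genes had peaks at 2 of 9, Satb2 and Runx2 (Fisher's exact test, adjusted p = 0.383), and tendon genes at 1 of 5, Scx at 19.6 (Fisher's exact test, adjusted p = 0.699).

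Genes of proliferating cells and housekeeping genes were frequently marked, at 11 of 12 and 14 of 16 (Fisher's exact test, adjusted p = 0.00142 and 0.000787). Ccnd2 had a fold of 21.1, Mycn 12.1 (7.94 and 9.07 in replicates 1 and 2) and Actb 41.1. Neither list passed against CpG-matched random lists (adjusted permutation p = 0.117 and 0.197). Immediate early genes had peaks at 7 of 12, led by Dusp1 at 18.2 (Fisher's exact test, adjusted p = 0.312).

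Genes of the apical ridge, the signalling epithelium at the limb margin, were seldom marked. Of the 14 apical ectodermal ridge genes, 1 had a replicated promoter peak, Sp6 at a fold of 3.43 (Fisher's exact test, adjusted p = 0.0309). Some members of the list encode FGF and WNT products that sustain outgrowth, and others, such as Sp6, Dlx5 and En1, encode transcription factors. Fgf8, the main ridge FGF gene, had none in any of the 4 lists. The list also fell below CpG-matched random lists (adjusted permutation p = 0.00465). The call depended on the list of peaks used: 4 of 14 had a peak in the pooled list (Fisher's exact test, adjusted p = 0.368), 3 in replicate 1 (0.166) and 7 in replicate 2 (1), and with a promoter window of 2.5 kb the adjusted p was 0.0994. Surface ectoderm genes had peaks at 3 of 15, Tfap2a at 10.1, Grhl2 and Cldn7 (Fisher's exact test, adjusted p = 0.261), against 6 in replicate 1, and were called lower with a 500 bp window (6.67%, Fisher's exact test, adjusted p = 0.0230). Genes of keratinised epidermis had a peak at 1 of 9, Krt10 at 17.0 (Fisher's exact test, adjusted p = 0.148). The Krt10 peak lay inside the gene (chromosome 11, 99385789 to 99386847), away from its 5' end at 99389364, and counted through a further annotated TSS.

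Genes of several other tissues had few replicated promoter peaks, for some lists near the number in CpG-matched random lists. No promoter peak was replicated for 9 macrophage genes (Fisher's exact test, adjusted p = 0.0330), 12 hepatocyte genes (0.00962), 10 endoderm genes (0.0217) or 1134 olfactory receptor genes (1.04e-259). Against CpG-matched random lists the macrophage and hepatocyte calls ended (adjusted permutation p = 0.912 and 0.468), while the endoderm and olfactory receptor lists stayed lower (0.00886 and 0.00207). By Fisher's exact test the endoderm and macrophage calls also ended at a −log10 q of 5 or more (adjusted p = 0.0506 and 0.0641) and with the pooled list (0.0600 and 0.0766), and the macrophage call with a 2.5 kb window (0.148) and in replicate 2 (0.0605). Neuronal genes had a peak at 2 of 17, Elavl4 and Pax6 (Fisher's exact test, adjusted p = 0.0506), and pluripotency genes at 1 of 12, Klf4 (0.0674), and both were lower than CpG-matched random lists (adjusted permutation p = 0.00620 and 0.0108). By Fisher's exact test both passed as lower with a 2.5 kb window (adjusted p = 0.0306 and 0.0430), with the pooled list (0.0162 and 0.0228) and in replicate 2 (0.0282 and 0.0179), and the neuronal list also with a 500 bp window (0.0449) and with replicated peaks overlapped by each replicate (0.0471). Germline genes had a peak at 1 of 10, Prm1 (Fisher's exact test, adjusted p = 0.107), cardiomyocyte genes at 2 of 13, Myl4 and Myh7 (0.147), erythroid genes at 2 of 11, Tfrc and Klf1 (0.294), and genes of neural crest, Schwann cells and melanocytes at 2 of 9, Mpz and Tfap2b (0.383). By Fisher's exact test the germline list passed as lower in replicate 1 (none of 10, adjusted p = 0.0173) and with replicated peaks overlapped by each replicate (none, 0.0256), and the cardiomyocyte list with a 500 bp window (7.69%, 0.0449). CpG-matched random lists had a mean of 1.97 marked genes for the erythroid list, 2.31 for the cardiomyocyte, 3.23 for the neural crest and 4.63 for the germline list. None of these 4 lists passed as lower against them. In the list of replicate 2, 5 of the 9 neural crest genes had a peak (55.6%, against 49.7% of all genes).

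Muscle and vessel cells enter the limb bud from outside. Muscle progenitor genes had a peak at 5 of 10, led by Six4 at 24.5 and Eya1 at 10.7, while Myf5 and Myod1 had none in the replicated list (Fisher's exact test, adjusted p = 0.592). Genes of differentiated muscle had a peak at 2 of 10, Mylpf at 10.8 and Myog, the myogenin gene, at 4.22 (Fisher's exact test, adjusted p = 0.383). Endothelial genes had a peak at 6 of 14, with Fli1 at 21.7, Erg at 5.68 and the VEGF receptor gene Kdr at 4.22 (Fisher's exact test, adjusted p = 1). The count was 7 in replicate 1 and 11 in replicate 2, and the folds were 11.2 and 18.1 at Fli1 and 5.81 and 3.18 at Erg.

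**Figure D2:**
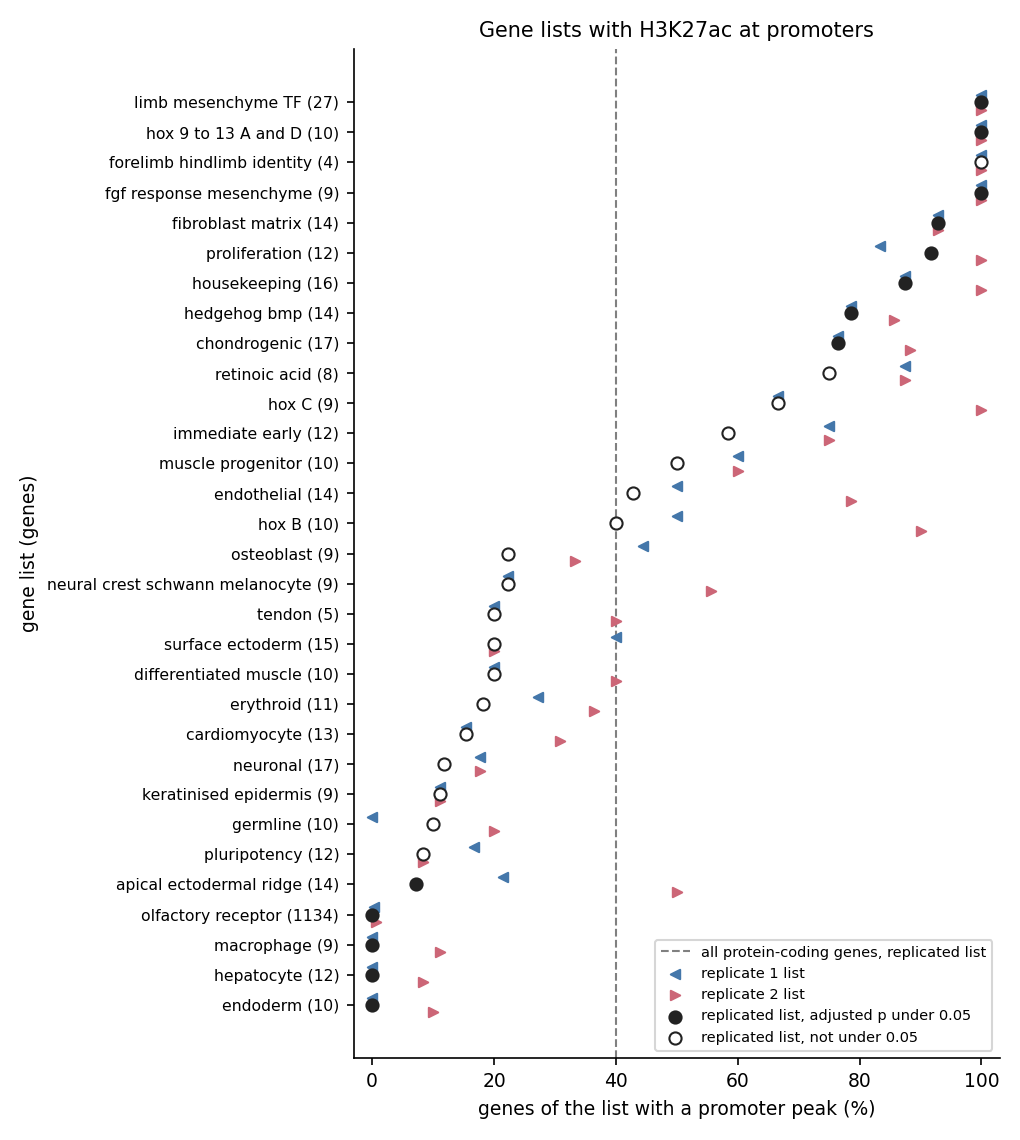
Share of the genes of each list (y axis, number of genes in parentheses) with an H3K27ac promoter peak (x axis, percent), with circles for the replicated list, filled where the adjusted p of Fisher's exact test was under 0.05, blue triangles for replicate 1, red triangles for replicate 2 and a dashed line at the 40.02% of all protein-coding genes. The limb transcription factor list lies at 100% in all 3, and the ridge list at 7.14%, 21.4% and 50%.

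Limb transcription factor genes were also surrounded by distal acetylation. They were the nearest TSS of 206 distal replicated peaks, 4.33 times the mean of 47.6 over 10000 random lists matched on the length of the gene's territory (two-sided permutation test, adjusted p = 0.00620), and 26 of the 27 genes had at least 1. The ratio was 2.42 against random lists matched on promoter peaks as well (adjusted permutation p = 0.0403). In the lists of replicates 1 and 2 these genes had 351 and 540 distal peaks, and the chondrogenic genes 191 and 302. Lmx1b, the dorsal limb selector gene, had 31, Sall1 22, Gli3 17, Pbx1 15, Prrx2 12 and Shox2 11, while Irx5 had none; apart from Gli3 and Shox2 these were named after their values were seen. Without the 3 genes with the most, 136 peaks remained against 41.0 (permutation p = 0.00340). Chondrogenic genes had 104 distal peaks against 21.3 (permutation test, adjusted p = 0.0393), of which 25 lay nearest to Sox9, 19 to Sox6 and 9 to Col2a1, with 21 at Wwp2 and 19 at Sox5, 2 genes named after their values were seen. Without the 3 genes with the most, the chondrogenic list had 39 against 15.3 (permutation p = 0.114), and it did not pass against lists matched on promoter peaks as well (adjusted permutation p = 0.130). Olfactory receptor genes had 19 distal peaks against 183 (permutation test, adjusted p = 0.00620).

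The other 28 lists did not pass this test. The FGF response list came closest from above, with 66 distal peaks against 15.2 (permutation test, adjusted p = 0.0682), of which 12 were nearest to Dusp6 and 11 to Fgfr2. The 4 forelimb and hindlimb genes had 30 against 7.05 (permutation test, adjusted p = 0.158), and neuronal genes had 2 against 18.3 (0.158). The posterior Hox list passed in the pooled list, at 10.7 times the random mean, as did the FGF list at 4.30 times and, below its random lists, the neuronal list at 0.0843 times (permutation test, adjusted p = 0.0455 for each). The posterior Hox list also passed in the list of replicate 1 (8.49 times, permutation test, adjusted p = 0.0279). Among all genes, Zfhx3, a large homeobox gene, had the most distal peaks, 71, followed by Zmiz1 with 58, Gse1 with 57, Mecom with 45, Dnm3 with 43, Tcf7l2, a mediator of WNT signalling, with 42, Zfp36l1 with 41, Kif26b and 4930558K02Rik with 38 each and Tenm4 with 37.

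**Figure D3:**
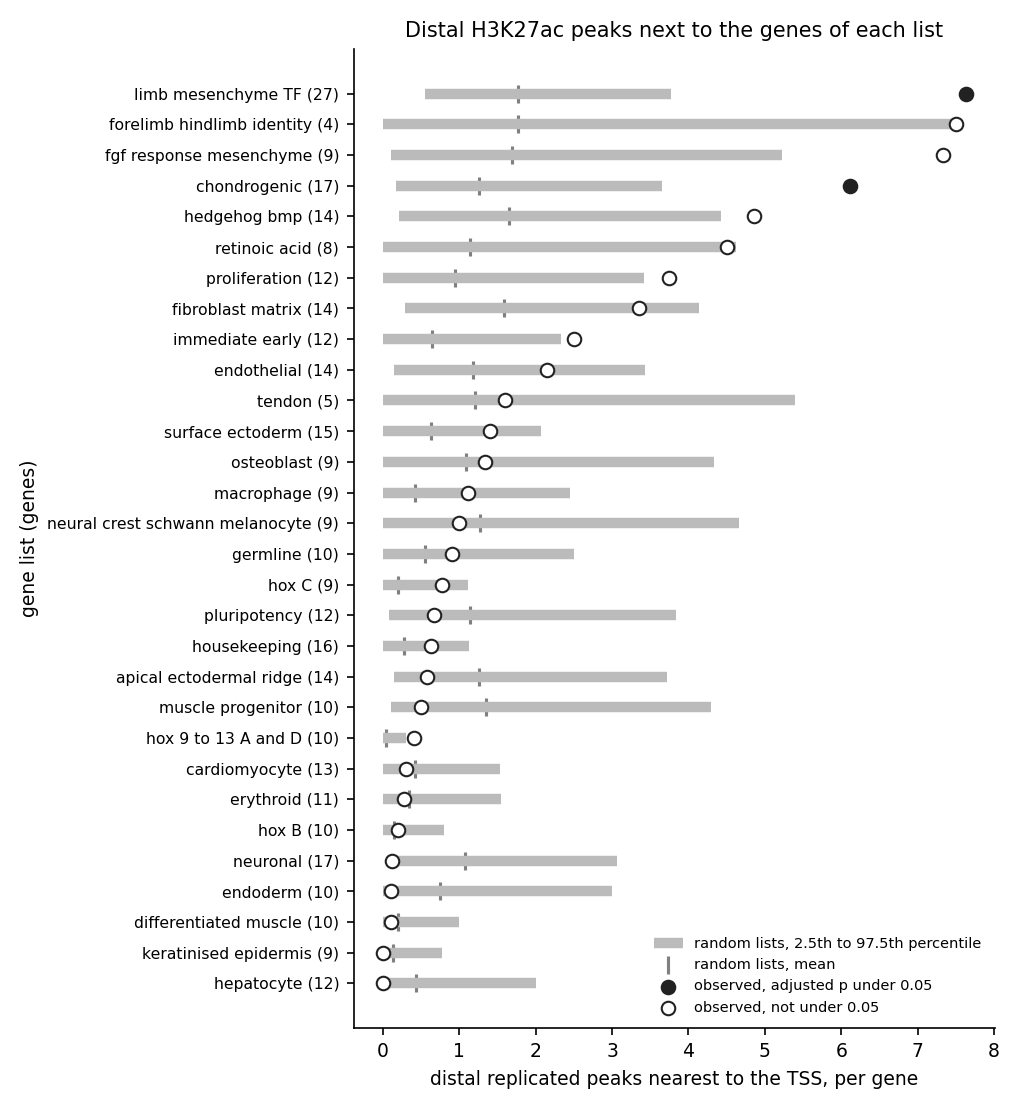
Distal replicated peaks per gene (x axis) for each gene list (y axis, number of genes in parentheses), with circles for the observed value, filled where the adjusted permutation p was under 0.05, grey bars for the central 95% of matched random lists and a grey tick at their mean. The limb transcription factor list lies at 7.63 peaks per gene against a mean of 1.76, and the chondrogenic list at 6.12 against 1.26; the olfactory receptor list, at 0.0168 against 0.161, is not drawn.

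Distal acetylation next to the genes of limb patterning differed widely between loci. Sox9 had 25 distal peaks, the farthest 821 kb from its TSS and the strongest, with a fold of 10.5, on chromosome 11 (113120707 to 113122343), 340 kb away. Gli3 had 17, Tbx4 16, Tbx5 8, Prrx1 6, Pitx1 5 and Fgf10, the mesenchymal FGF gene that starts outgrowth, 5. At Tbx4 the strongest distal peak had a fold of 13.9 (chromosome 11, 85915983 to 85919145) and lay 21.6 kb from the TSS. At Pitx1 it had a fold of 11.8 and lay 127 kb away (chromosome 13, 55962112 to 55963395). Grem1 had 1, and Shh and Fgf8 had none; in the lists of replicates 1 and 2 these counts were 2 and 9 at Grem1, 3 and 2 at Shh and 3 and 0 at Fgf8. At the other loci the single lists held more than the replicated list, with 44 and 69 at Sox9, 27 and 46 at Gli3, 28 and 37 at Tbx4, 15 and 29 at Tbx5, 8 and 14 at Prrx1, 14 and 21 at Pitx1 and 11 in each at Fgf10. The territories ran from 44.8 kb at Fgf8 to 1250 kb at Sox9, so the counts do not compare loci at equal length. In Lmbr1, whose introns hold a remote limb enhancer of Shh, intron 5 carried 1 replicated peak with a fold of 3.88 (chromosome 5, 29313743 to 29314127), called at a summit height of 9 fragments in replicate 1 and 6 in replicate 2. Whether this peak overlaps the enhancer was not examined. The only other Lmbr1 intron with a peak was intron 1, where a peak with a fold of 3.43 reached into the promoter.

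The Hoxa and Hoxd clusters and their flanks were densely marked. Replicated peaks covered 54.8 kb of the 105 kb Hoxa cluster (chromosome 6, 52155590 to 52260880) and 33.0 kb of the 96.8 kb Hoxd cluster (chromosome 2, 74668310 to 74765142), compared with 33.2 kb of 116 kb at Hoxc and 7.93 kb of 174 kb at Hoxb. The 1 Mb beyond Hoxa13 held 54 distal peaks, more than 99.5% of 2625 tiles of 1 Mb, of which the median was 2. Of these 54, 45 lay in the body of Jazf1, a gene named after its values were seen, and the strongest, with a fold of 14.8, lay 705 kb from the cluster (52965131 to 52966508). The 1 Mb beyond Hoxa1 held 23. Beside Hoxd, the sides of Hoxd13 and Hoxd1 held 26 and 25 distal peaks, above 95.7% and 95.3% of tiles. The 1 Mb beyond Hoxb13 was as dense, with 28, above 96.5% of tiles, the strongest with a fold of 43.2, while that beyond Hoxb1 held 5, and the sides of Hoxc13 and Hoxc4 held 17 and 11. The lists of replicates 1 and 2 held more on every side: 77 and 99 beyond Hoxa13, 44 and 64 beyond Hoxa1, 44 and 65 beyond Hoxd13, 46 and 71 beyond Hoxd1, 48 and 76 beyond Hoxb13, 19 and 34 beyond Hoxb1, 28 and 51 beyond Hoxc13 and 18 and 38 beyond Hoxc4.

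**Figure D4:**
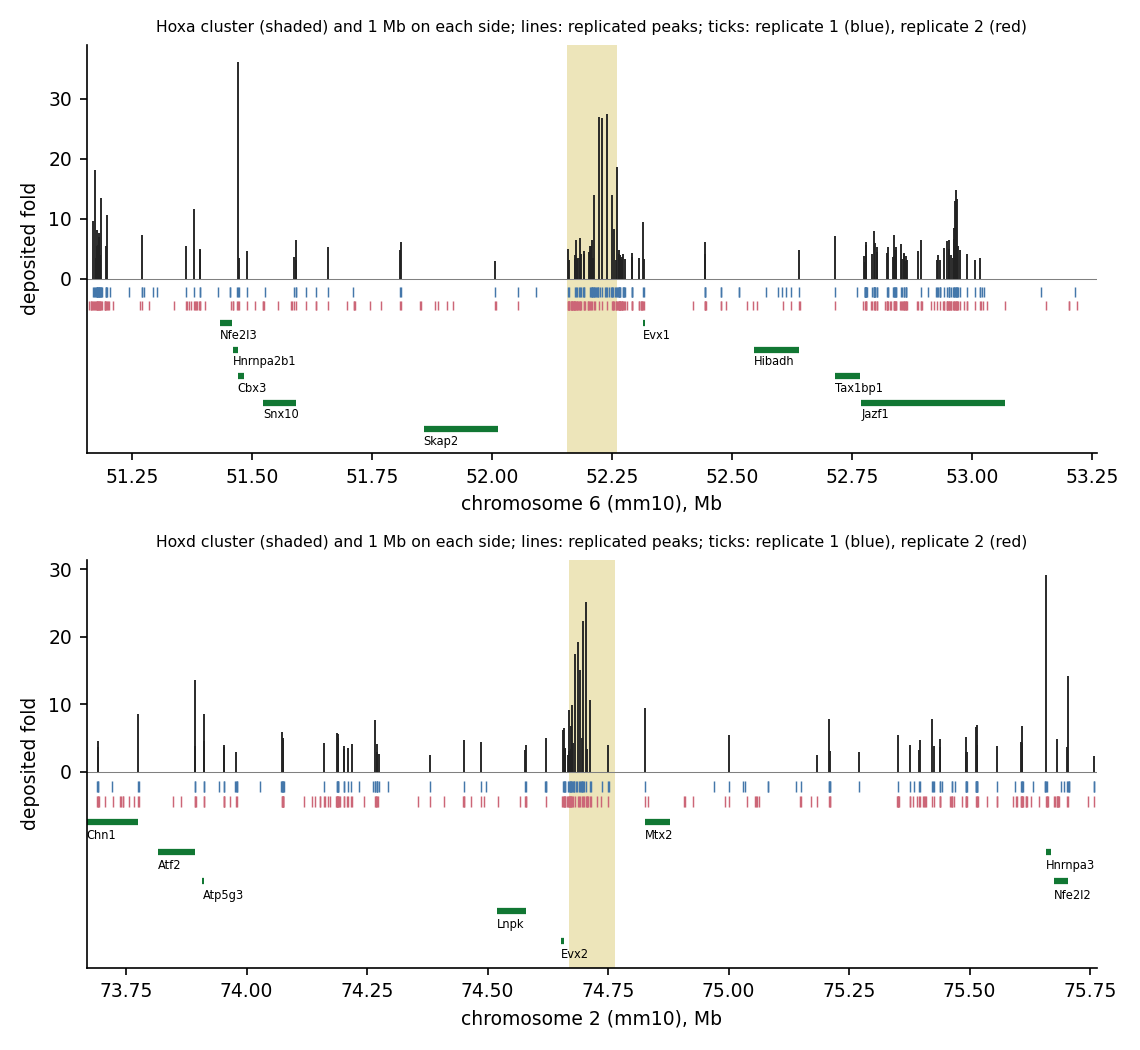
Replicated H3K27ac peaks at the Hoxa cluster (top) and the Hoxd cluster (bottom) with 1 Mb on each side, with position on mm10 in Mb on the x axis, the deposited fold as black lines on the y axis, ticks for the peaks of replicate 1 (blue) and replicate 2 (red), the cluster shaded and other protein-coding genes in green. The clusters hold peaks up to a fold of 27.4 at Hoxa and 25.1 at Hoxd, and 45 distal peaks lie in Jazf1.

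Distal peaks stitched over short gaps gave 7364 clusters, of which 4446 held a single peak and 82 held 10 or more. The cluster with the longest summed peaks, 26.9 kb in 32 peaks, lay on chromosome 11 (99054396 to 99150461) across Tns4 and Ccr7. The nearest protein-coding TSS beyond it was that of Ccr7, at 4.615 kb. On the other side it was that of Igfbp4, which encodes a binding protein of insulin-like growth factors, at 7.08 kb. Dnm3, a dynamin gene, held the second and the fifth (chromosome 1, 162010373 to 162054390 and 162071238 to 162164586), with 26.2 kb and 20.1 kb. The third, 21 kb, lay between Ubash3b and Sorl1 (chromosome 9, 41897987 to 41954154), and the fourth between Acot11 and Ssbp3. The others of the 10 longest lay in or beside Gse1, Ror2, which encodes a receptor for WNT ligands in skeletal growth, Capzb, Trio, and Prrx2 with Ptges. Each of the 10 was made up of 12 or more peaks. With other stitching distances or a single replicate's list, between 4 and 6 of these 10 overlapped the new 10 longest.

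Some sequence motifs differed in share between distal peaks and nearby sequence of similar GC content. The E-box form bound by myogenic factors and their relatives was found within 500 bp windows at the summits of 34.3% of 12932 distal peaks and in 26.5% of control windows (odds ratio 1.45, Fisher's exact test, adjusted p = 5.89e-42). Of the motifs that passed, the homeodomain core motif followed (odds ratio 1.29), then the GC box of SP and KLF factors (1.27), the SOX motif (1.24), the TCF/LEF motif of WNT signalling (1.22) and the ETS motif (1.18). All 6 had odds ratios above 1 in the list of each replicate, from 1.07 to 1.31. Lower shares were found for the CTCF motif (0.513), the TWIST-type E-box (0.765), NFY (0.776), POU (0.788), GATA (0.820) and RUNX (0.941). By Fisher's exact test the other 12 of the 24 motifs did not pass, among them GLI (odds ratio 1.07, adjusted p = 0.769), posterior HOX (1.23, 0.0705), PBX (0.873, 0.294), MEIS (0.944, 0.0589) and T-box (0.933, 0.208). Of these, posterior HOX passed with 1 kb windows (1.46, Fisher's exact test, adjusted p = 4.24e-08) and in the lists of replicate 1 (1.35, 2.67e-05) and replicate 2 (1.26, 1.62e-05), as did MEF2 in the same settings (1.74, 1.63 and 1.47). PBX was lower and passed in 4 of the 5 other settings, with odds ratios from 0.627 to 0.842. The general E-box, GLI, LIM homeodomain, MEIS, T-box and TEAD motifs also passed in at least 1 of them. The homeodomain and TCF/LEF odds ratios fell to 0.753 and 0.964 when control windows were not matched on GC, and the calls for CTCF, TWIST, POU and RUNX ended when repeats were left out. POU also lost its call with 1 kb windows (0.936, Fisher's exact test, adjusted p = 0.316) and in the list of replicate 1 (0.916, 0.154). RUNX kept its call in none of the 5 other settings.

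**Figure D5:**
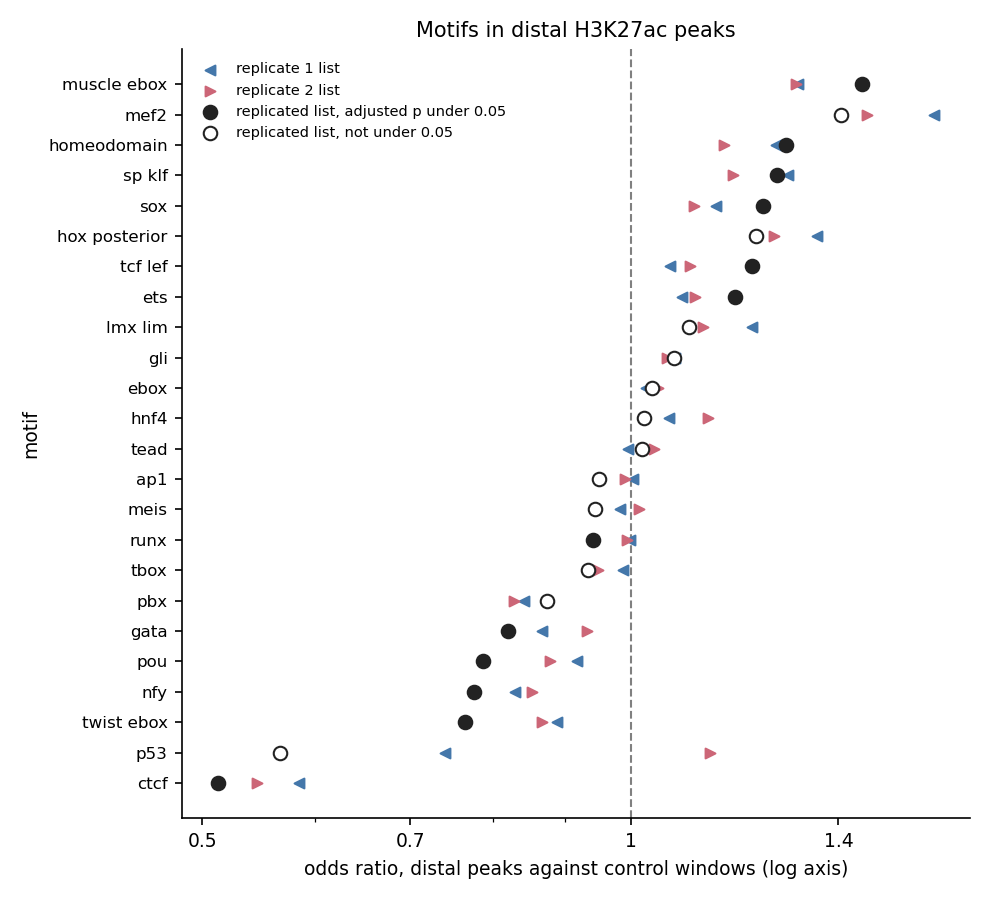
Odds ratio of each motif (y axis) in distal H3K27ac peaks against GC-matched control windows (x axis, log scale), with circles for the replicated list, filled where the adjusted p of Fisher's exact test was under 0.05, blue triangles for replicate 1, red triangles for replicate 2 and a dashed line at 1. Among the circles, the E-box bound by myogenic factors lies highest at 1.45 and the CTCF motif lowest at 0.513.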

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

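The tests of coverage, of enrichment, of a −log10 q of 20 and of a summit height of 10 were chosen only after the result was seen; the others were set before.

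Peaks on scaffolds not placed on a chromosome were left out of all overlaps, gene and motif comparisons, while the numbers of listed peaks and their ratios include them. They numbered 6 in the list of replicate 1, 6 in that of replicate 2, 8 in the pooled list and 4 in the replicated list. The strongest was on an unplaced scaffold of chromosome 4, with a fold of 20.7 in the replicated list, 15.6 in replicate 1 and 21.4 in replicate 2.

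Replicate 2 listed 1.52 times as many peaks as replicate 1. Extra calls near the threshold stayed open: the ratio was 1.37 at a −log10 q of 5 or more, between the bounds set beforehand, and 1.60 at 20 or more, but replicate 2 held fewer peaks with summits of 10 fragments or more (22030 against 24668, ratio 0.893), and neither limit is the same threshold at different backgrounds. Deeper coverage stayed open too, as the lowest background level in replicate 2 was 0.734 times that of replicate 1 but may come from a control. A candidate explanation is stronger enrichment over background in replicate 2, where the median ratio of folds was 1.35 over shared promoter peaks with a −log10 q of 5 or more in both replicates and 1.27 over all overlapping peaks, although the fold also contains this background. Whether it came from the immunoprecipitation, the background or the embryos was not tested.

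Promoter peaks at all 27 limb transcription factor genes could follow from CpG-rich promoters, which are often acetylated. Random lists matched on promoter CpG ratio argued against this as the whole cause (adjusted permutation p = 0.00207). For the distal peaks of the same genes, large territories were argued against by a density of 20.9 peaks per Mb, above the 95th percentile of matched lists (8.74). A draw of peaks to any acetylated promoter, whatever its strength, was argued against as the whole cause by lists matched on having one. They lowered the ratio of observed to random peaks from 4.33 to 2.42 and left it close to the threshold (adjusted permutation p = 0.0403). These lists were not matched on promoter fold, whose median was 13.4 in the limb list and 7.39 over all genes with a promoter peak. A draw that grows with promoter strength therefore stayed open. With 1 tissue and stage, no biological explanation was tested.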

How the results depend on the processing

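The settings with repeats left out, a summit height of at least 10 fragments, replicated peaks overlapped by a peak of each replicate and a −log10 q of 20 were chosen after seeing the data. Samples could not be paired between groups because the design has only 1 group. Each motif control window was drawn for 1 peak window, and Fisher's exact test did not use this pairing.

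Stricter lists held 28614 and 10719 peaks of replicate 1 and 42467 and 14719 of replicate 2 at a −log10 q of 2 and 5. The ratio of replicate 2 to replicate 1 was 1.48, 1.37 and, at 20, 1.60. The rank correlation of folds was 0.786 for overlaps of 50% of both peaks, 0.681 for promoter and 0.479 for distal peaks. The share of replicated peaks found in both replicates was 86.7% at 50% of the shorter peak and 61.6% at 50% of both. Against CpG-matched random lists 8 promoter lists were called, in place of 13, and 6 of the 13 were kept. Distal lists called higher numbered 4 with the pooled list and 1 when matched on promoter peaks, in place of 2. The number of clusters lay between 15942 and 22321 with single replicates. Among gene lists the direction turned with replicate 2's list: at ridge promoters to 50% against 49.7% of all genes (Fisher's exact test, adjusted p = 1), the share in replicate 1 being 21.4% against 43.2%, and at Hoxb promoters, which had no direction before (40% against 40.02%), to 90% (Fisher's exact test, adjusted p = 0.0268). Taken from another list, the promoter folds of named genes stayed within the SD of the replicates in 226 cases and did not in 122, which include genes with a peak in 1 replicate only. Each replicated peak had the coordinates of a pooled peak, so comparisons with the pooled list could hardly differ. The 226 cases include these and do not measure how far folds held between the replicates. Without GC matching the odds ratios of the homeodomain (0.753), TCF/LEF (0.964) and LIM homeodomain (0.581) motifs reversed; the cause was not tested.

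The limb transcription factor list kept its call in all 8 promoter and 7 distal alternatives, with adjusted p up to 0.00207 and 0.0403, as did the fibroblast and matrix list at promoters (up to 0.00473). The chondrogenic list reached 0.182 and 0.130. Summits under 10 fragments, 53.04% and 72.3% of the replicates' peaks, limit what can be said of weak peaks.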

Other observations

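The tests of CpG-poor ridge promoters and of weak peaks against CpG-matched genes were chosen only after the results were seen.

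Several groups had more marked promoters in single lists than in the replicated list. Among genes without a replicated promoter peak, 21.2% had one in another list. The share was 5 of 6 for Hoxb genes, 6 of 8 for endothelial genes and 8 of 13 for ridge genes (Fisher's exact test, adjusted p = 0.0162 for each of the 3). The Hoxb genes were marked in replicate 2, with Hoxb5 at a fold of 5.18, Hoxb6 at 3.69 and Hoxb13 at 2.67. The endothelial genes Emcn (3.18) and Esam (3.50), which encode proteins of the vessel surface, were also marked in replicate 2, and Cldn5 in both replicates (2.26 and 2.997). Against CpG-matched genes none of 28 such comparisons passed, the adjusted permutation p being 0.265 for Hoxb and 0.213 for endothelial genes in any other list. Of the epithelial genes, Cdh1 had a peak in replicate 1 alone, at a fold of 3.27, and Epcam one in replicate 1, at 3.64, and in the pooled list.

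One hypothesis was that ridge genes may be acetylated too weakly for the replicated list, as when a small share of the cells is marked. In all, 9 of the 14 had a promoter peak in the pooled list or in one of the replicates, the number this hypothesis asked for beforehand being at least 7. That test was not specific: of the 13 without a replicated peak 8 had another one, against a mean of 5.09 for CpG-matched genes (permutation p = 0.158), so weak acetylation and the weak calls of any CpG-rich promoter cannot be told apart with these few genes. CpG-poor promoters were argued against by CpG-matched random lists (adjusted permutation p = 0.00465).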
